A study of Arabidopsis thaliana and Marchantia polymorpha and Mesotaenium endlicherianum with 120 samples.

How the data were processed

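Transcripts were measured by RNA-seq in the flowering plant Arabidopsis thaliana, the liverwort Marchantia polymorpha and the algae Mesotaenium endlicherianum and Ostreococcus tauri, each grown at 16 or 24 °C in continuous white light of 10 or 100 µmol per square metre and second. The Arabidopsis and Marchantia tables held a wild type and 3 mutant lines, and the 2 algal tables a wild type alone, with 3 libraries in each of 40 groups. RNA of Arabidopsis, Marchantia and Mesotaenium was extracted with the NucleoSpin RNA Plant kit, per the labels' protocols, which do not say how Ostreococcus RNA was extracted. Libraries were made and sequenced by BGI as paired reads of 100 bases on DNBseq, per the labels' protocols. FastQC 0.11.5 and HISAT2 2.1.0 are named in the submitters' processing notes. The counting program, the genome builds, the annotations and any use of strand are not given in the sources used here. The deposited tables hold whole-number counts per gene and library, 1 table per species, with no normalization found in the values. The tables had 32833, 20574, 11119 and 7833 genes for Arabidopsis, Marchantia, Mesotaenium and Ostreococcus, of which 3604, 1651, 304 and 2 had no counts in any library. No library was left out, and no pair of libraries within a group had counts as close as repeated sequencing of 1 library would give.

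Each species was fitted on its own with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with 1 mean per group over all libraries of the species. Genes were kept by filterByExpr with its default minimum count of 10, which left 22828, 15432, 10736 and 7667 genes. Library sizes were scaled by TMM, with factors from 0.501 to 1.51 in Arabidopsis, and dispersions and quasi-likelihood fits were robust. The common biological coefficients of variation were 0.204, 0.139, 0.111 and 0.122, with 32 residual degrees of freedom for Arabidopsis and Marchantia and 8 for each alga. Quasi-likelihood F tests were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Adjusted p-values marked edgeR in the text are these. Errors of log2 changes are standard errors from the F statistic, and errors of CPM (counts relative to TMM-scaled library sizes) are SDs over 3 libraries. Higher means higher at 24 than at 16 °C, at light 100 than at light 10, and in a mutant than in its wild type.

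In each wild type the comparisons were temperature at each light, light at each temperature, and their interaction. Each mutant was compared with its wild type for the average over the 4 conditions and for the temperature effect, the light effect and the interaction, each tested as a difference between lines. Average effects of a wild type were means over the other factor. Correlations are across genes, with jackknife errors over libraries, and values for mutants that share a wild type stand beside 10 simulations of unchanged lines and 6 splits of the wild-type libraries. The share of a wild-type response kept by a mutant is the median over genes of the mutant's average effect divided by the wild type's, on the log2 scale, for the genes called for that average effect in the wild type. A fold change against a group with no counts is a lower bound, taken against 3 counts over the group.

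For Arabidopsis, 14 gene lists were fixed before the data were examined, for growth targets of shade and PIF factors, antenna, chlorophyll synthesis, light signalling, photoprotection, flavonoid, heat-shock, cold-response, clock, Calvin cycle, cell-cycle, salicylate defence, root marker and seed reserve genes. Growth genes in the text are members of the list of growth targets, whether a member promotes or restrains growth. Lists were tested with camera, with a preset correlation between genes of 0.01 and with an estimated one, adjusted over the lists of a comparison. In 24 of 238 list tests the median, the mean and the test differed in sign, and 0 of these were called. Chosen after seeing the data were 3 more lists, for aliphatic and indole glucosinolate synthesis and for jasmonate and touch genes. Gene names came from the TAIR10.1 gene table, in which 32548 of the 32833 Arabidopsis identifiers were found and 10804 had a symbol of their own. For Marchantia no name was given, and for the algae only the names in the tables themselves.

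The genes to name were set by a rule before the data were examined. In Col-0 it took the 6 highest and 6 lowest log2 changes among called genes with a symbol and a mean of at least 5 CPM, without overlap of replicates in the simple effects, and the 4 members with the smallest adjusted p of each called list. In mutants it took 6 and 6 for the average and 3 and 3 for the other differences, with the mutated genes always included. In the other species it took at most 2 identifiers up and 2 down, or 6 and 6 for entries with names. Changes called largest in the text are so among the genes this rule admits. Genes whose value or call rested on 1 library are named with the value without it or left out. Some genes with near-identical copies, whose reads the counting could split, are marked as uncertain. The absence of such a mark, as for LHCB2.1 and LHCB2.2, is no sign that a gene has no such copy.

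Alternatives set before the data were examined were DESeq2 1.42.0 with its own size factors, RLE scaling in edgeR, no low-count filter, the replicate number as a block, fits on the compared lines alone, an estimated correlation for the lists and leaving out each library in turn. Chosen after seeing the data were leaving out the rRNA genes, the log2 share of rRNA counts as a covariate, leaving out together the 2 Ostreococcus libraries with the fewest counts, and the antenna list without LHB1B2. All libraries of a species share 1 estimate of the spread per gene, so a group left with 2 libraries is assumed to vary like the others. Other splits of the libraries numbered 10 for each simple effect, and for interactions and mutants 25 (Arabidopsis) or 31 (other species), the real one included.

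The fits were tested on simulated counts drawn from each gene's mean over all libraries of a species, scaled to the library sizes. Dispersions were the trended ones, and 200 genes above a minimum mean count were changed. No real light, temperature or line effects were in these counts, so the shares below may not hold for the real fits. For a 1.5-fold change, 11.9% of the changed genes were recovered in Arabidopsis Col-0 for warmth at light 10 and 2.99% for the interaction. For a 2-fold change, 67.2% of the changed genes were recovered in Arabidopsis Col-0 (warmth at light 10, 22371 genes) and 41.8% for the interaction, and for a 4-fold change 93.9% and 81.8%. For warmth at light 10, a 2-fold change was recovered for 80.6% of changed genes in Marchantia (15007 genes), 95.5% in Mesotaenium (10718 genes) and 95.5% in Ostreococcus (7650 genes). A 1.5-fold change was recovered for 55.2%, 82.1% and 80.6% of them. In these runs for warmth at light 10, genes that had not been changed made up 5 of 120 calls in Arabidopsis, 11 of 167 in Marchantia (6.59%), 17 of 202 in Mesotaenium (8.42%) and 8 of 192 in Ostreococcus, so the share was above 5% in Marchantia and Mesotaenium. It was also above 5% for the interaction in Marchantia (5.34%) and Mesotaenium (7.14%) and for the average difference of Atpif4-2 (5.67%), and with DESeq2 for warmth at light 10 it was 10.1%, 7.74%, 11.5% and 7.54% in Arabidopsis, Marchantia, Mesotaenium and Ostreococcus. For warmth at light 100 in the same simulated counts, where no gene had been changed, 0 genes were called in each species. A share of 0.5 put in came back as 0.474 for Atpif4-2 (161 genes called of 22389 tested) and 0.505 for Mppif-1 (179 called of 14996 tested). Of 14 lists tested with 1 doubled, that list was called and 0 others were. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.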

Results

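RNA-seq counts were deposited for 4 organisms of the green lineage grown in continuous white light of 10 or 100 µmol per square metre and second (light 10 and light 100 from here on) at 16 or 24 °C. The flowering plant Arabidopsis was sampled as seedlings of 7 days, with 2 days at 20 °C and light 100 before 5 days of treatment, in Col-0 and the lines Atpif4-2, Atphyb-9 and Athy5-2. The liverwort Marchantia was sampled as thalli of 10 days in TAK-1 and the lines Mppif-1, Mpphy-1 and Mphy5-1. The algae Mesotaenium (10 days) and Ostreococcus (7 days) were sampled as wild types. Each of the 40 groups held 3 libraries, 120 in all. Total counts per library ran from 30806701 to 44043446 in Arabidopsis, 40041739 to 44085211 in Marchantia, 30958900 to 36785161 in Mesotaenium and 18415316 to 38801166 in Ostreococcus. Nuclear and organellar rRNA genes held a median of 5.71% of the counts in Arabidopsis libraries at light 10 (0.667% to 21.8%) and 0.547% at light 100 (0.302% to 9.37%), and most at light 10 and 24 °C in Athy5-2 (19.2% ± 2.66, SD, n = 3).

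**Figure D1:**
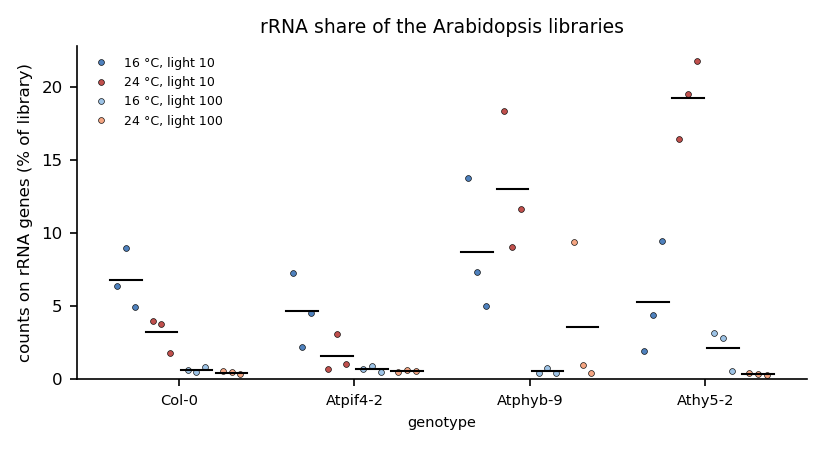
Each point is the share of 1 Arabidopsis library's counts on rRNA genes, in percent, by genotype, temperature and light, and the short lines are means of 3 libraries. The Athy5-2 libraries at 24 °C and light 10 averaged 19.2%, against 0.344% at light 100.

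The transcripts of the 3 mutated Arabidopsis genes were checked first. PIF4 (AT2G43010) was lower in Atpif4-2 than in Col-0 at 16 °C and light 10 (25.3 ± 3.76 against 51.4 ± 0.913 CPM, mean ± SD, n = 3), at 24 °C and light 10 (25.9 ± 3.40 against 85.5 ± 6.15 CPM) and at 24 °C and light 100 (20.1 ± 1.69 against 73.2 ± 11.1 CPM). At 16 °C and light 100, where Col-0 itself held 11.7 ± 0.997 CPM, the difference was -0.17 ± 0.142 on the log2 scale (SE; edgeR adjusted p = 0.676). PHYB (AT2G18790) was lower in Atphyb-9 in all 4 conditions, by log2 differences from -1.19 ± 0.0980 at 16 °C and light 100 to -0.34 ± 0.0967 at 24 °C and light 100. At 16 °C and light 10 it ran from 26.8 to 29.7 CPM in Atphyb-9 and from 24.1 to 31.9 CPM in Athy5-2. PHYB therefore did not tell these 2 lines apart there. HY5 (AT5G11260) was lower in Athy5-2 at 24 °C (1.74 ± 0.132 against 6.80 ± 0.703 CPM at light 100) and at 16 °C and light 100, and at 16 °C and light 10 its difference was -0.20 ± 0.168 (edgeR adjusted p = 0.406). The counts separated Atpif4-2 from Col-0 by PIF4, and Athy5-2 from Col-0 by HY5, in 3 of the 4 conditions each, and the libraries of the remaining condition were taken by their labels. Targeted Marchantia genes were not checked here, since the files do not pair Marchantia identifiers with names.

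**Figure D2:**
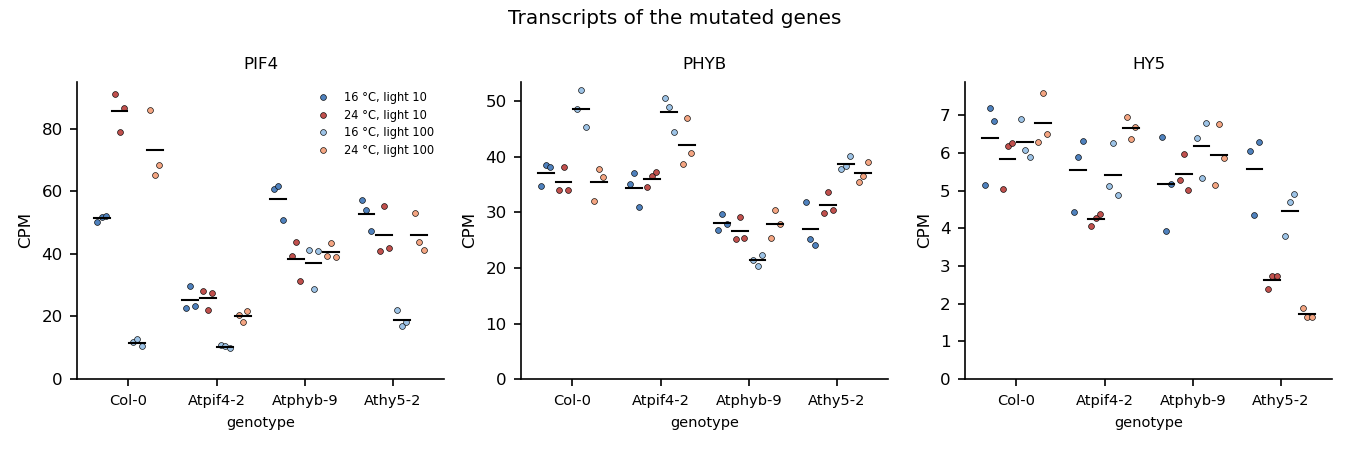
Each point is 1 Arabidopsis library's CPM of PIF4, PHYB or HY5 (linear axis from 0), by genotype, temperature and light, and the short lines are means of 3 libraries. PIF4 in Col-0 rises from 11.7 CPM at 16 °C and light 100 to 73.2 CPM at 24 °C and light 100.

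Warmth at light 10 lowered cold-response genes and raised growth genes of the shade and PIF list in Col-0. COR15A (AT2G42540) fell from 7.35 ± 0.495 CPM at 16 °C to 0.362 ± 0.0630 CPM at 24 °C, and 16 of the 18 cold-response genes were lower (median log2 change -1.79). ADS1 (AT1G06080), a fatty acid desaturase gene, rose from 2.04 ± 0.412 to 20.2 ± 2.96 CPM, a log2 change of 3.31 ± 0.255 (edgeR adjusted p = 1.41e-12). Of the 19 growth genes 14 were higher and none was lower, among them HFR1 (AT1G02340; 2.00 ± 0.239) and PRE1 (AT5G39860; 2.54 ± 0.325). Growth genes are named for their list, which does not set whether a member promotes or restrains growth. Aliphatic glucosinolate genes, in a list drawn up after the data were seen, were lower as well.

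Among the cold-response genes, LTI78 (AT5G52310) changed by -3.15 ± 0.169 (edgeR adjusted p = 5.92e-18), COR15B (AT2G42530) by -4.16 ± 0.249 and KIN2 (AT5G15970) was 4.28-fold lower. COR15A and COR15B, and KIN2 and KIN1, are near-identical pairs, so the split of reads within each pair is uncertain. The seed and stress genes LEA18 (AT2G35300; 2.85 ± 0.350) and HIS1-3 (AT2G18050; 2.38 ± 0.270), the chaperone gene HSP90.1 (AT5G52640; 2.85 ± 0.415) and VSP2 (AT5G24770; 2.83 ± 0.409) were among the genes with the largest increases. MES18 (AT5G58310), a methyl esterase gene, had no counts at 24 °C and was at least 20.5-fold lower than at 16 °C (0.477 ± 0.199 CPM). The glucosinolate genes CYP79F1 (AT1G16410) and FMO GS-OX3 (AT1G62560) fell from 6.58 ± 1.15 to 0.0507 ± 0.0879 CPM and from 2.45 ± 0.678 to 0.113 ± 0.0996 CPM. The fitted change of CYP79F1 was -6.85 with all libraries, and without replicate 3 at 24 °C and light 10, which held the 7 counts of that group, it was at least 182-fold lower. Flavonoid genes were lower in 6 of 16 cases, with TT5 (AT3G55120) at -0.78 ± 0.140 and F3H (AT3G51240) at -1.14 ± 0.232. Of 22 clock genes 9 were higher and 3 lower (adjusted p = 0.315 with an estimated correlation), with FKF1 (AT1G68050; -1.20 ± 0.168) and PRR5 (AT5G24470; -0.90 ± 0.129) among the lower ones. The Calvin cycle list, with 7 of 14 genes lower (adjusted p = 0.581 with an estimated correlation), lost its call without replicate 3 at 16 °C and light 10. Adjusted over the list alone, 14 growth genes and 13 clock genes were higher and 16 cold-response and 7 flavonoid genes were lower. PIF4 itself rose by 0.74 ± 0.138 (edgeR adjusted p = 9.27e-05). In all, 5213 of 22828 genes were called, 2610 higher and 2603 lower at 24 °C.

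At light 100, warmth raised PIF4 and its growth targets, clock genes and antenna genes, and lowered flavonoid, cold-response and cell-cycle genes in Col-0. With an estimated correlation between genes, the antenna and cell-cycle lists were not past the threshold (adjusted p = 0.129 and 0.0836). PIF4 rose from 11.7 ± 0.997 to 73.2 ± 11.1 CPM (log2 change 2.65 ± 0.147, edgeR adjusted p = 1.45e-17). MYBL2 (AT1G71030), which encodes a repressor of anthocyanin genes, rose from 11.3 ± 2.68 to 122.7 ± 11.9 CPM, while 13 of 16 flavonoid and anthocyanin genes fell (median -2.16). KIN1 (AT5G15960) fell from 26.7 ± 2.17 to 0.861 ± 0.428 CPM, a log2 change of -4.95 ± 0.498. Of the 22 clock genes 19 were higher and none was lower (median 0.67).

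HFR1 (3.04 ± 0.265), PRE1 (3.76 ± 0.355) and SAUR20 (AT5G18020; 2.81 ± 0.338) led the 12 of 19 growth genes that rose, with SAUR20 sharing reads with near-identical SAUR genes. LCL1 (AT5G02840; 1.48 ± 0.114) led the clock genes, and PIL6 (AT3G59060; 1.38 ± 0.115), STO (AT1G06040; 1.36 ± 0.105) and PIL5 (AT2G20180; 1.28 ± 0.130) the light-signalling genes, a list with an adjusted p = 0.0836 with an estimated correlation. The antenna genes LHCA1 (AT3G54890), LHCA4 (AT3G47470) and LHCB3 (AT5G54270) rose by 1.27 ± 0.122, 1.52 ± 0.153 and 1.27 ± 0.131, with 13 of 17 antenna genes higher (adjusted p = 0.129 with an estimated correlation). Among the flavonoid genes, UF3GT (AT5G54060) changed by -3.15 ± 0.430 and F3H by -1.72 ± 0.226. ELIP2 (AT4G14690), a light-stress gene, fell from 55.0 ± 5.47 to 8.96 ± 1.18 CPM, and MES18 from 46.7 ± 5.53 to 2.92 ± 1.41 CPM. TPX2 (AT1G65970; 4.21 ± 0.336), CYP89A9 (AT3G03470; 3.02 ± 0.290) and CYP71A12 (AT2G30750; 3.18 ± 0.711) were among the largest increases, and BCS1 (AT3G50930; -3.76 ± 0.630) among the largest decreases. TPX2 has a near-identical copy, TPX1, so its reads are uncertain. Of the 13 cell-cycle genes 11 fell, among them PCNA1 (AT1G07370; -1.12 ± 0.175), as did 9 of 14 Calvin cycle genes, among them SBPASE (AT3G55800; -0.81 ± 0.0918). With an estimated correlation these lists had an adjusted p = 0.0836 and 0.239. Photoprotection genes went both ways, with 2 higher and 7 lower of 13 (adjusted p = 0.167 with an estimated correlation), and the test of that list lost its call without replicate 3 at 24 °C and light 100. Adjusted over the list alone, the genes past the threshold were 20 clock genes, 13 antenna genes and 14 light-signalling genes higher, and 14 flavonoid genes, 12 cold-response genes and 12 cell-cycle genes lower. In all, 8201 genes were called, 4322 higher and 3879 lower at 24 °C.

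**Figure D3:**
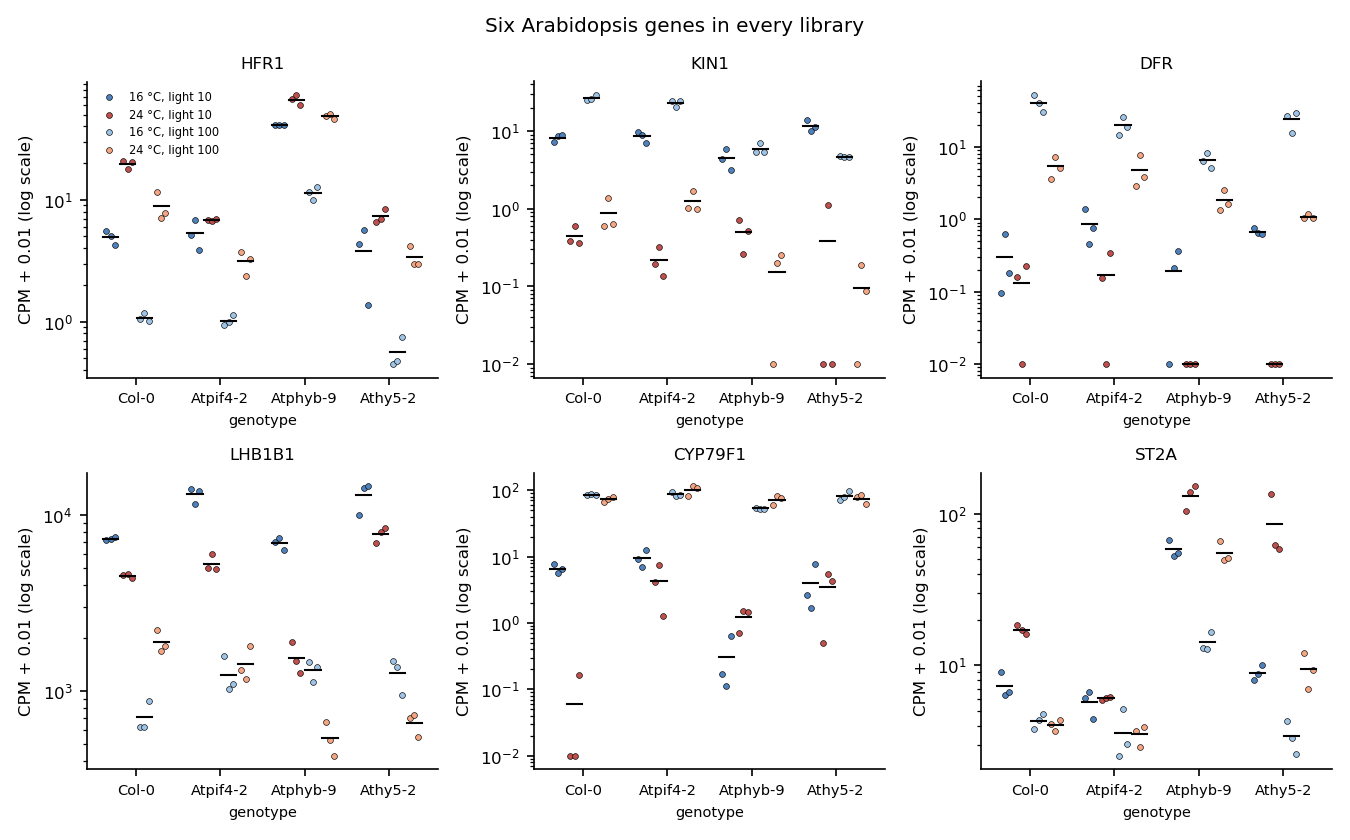
Each point is 1 Arabidopsis library's CPM plus 0.01 (log axis) of HFR1, KIN1, DFR, LHB1B1, CYP79F1 or ST2A, by genotype, temperature and light, with short lines at the means of 3 libraries. KIN1 in Col-0 averages 26.7 CPM at 16 °C and light 100 and 0.861 CPM at 24 °C and light 100.

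More light at 16 °C raised all 16 flavonoid and anthocyanin genes in Col-0 and lowered most antenna and growth genes. TT4 (AT5G13930), the chalcone synthase gene, rose from 53.3 ± 16.8 to 520.8 ± 55.8 CPM, and the list's median log2 change was 3.60. LHB1B1 (AT2G34430), an antenna gene, fell from 7294 ± 136.9 to 708.2 ± 143.6 CPM, and 15 of 17 antenna genes were lower (median -1.28). With an estimated correlation the antenna list had an adjusted p = 0.0496, and 0.0566 without LHB1B2 (AT2G34420), an antenna gene with uneven counts. PIF4 fell from 51.4 ± 0.913 to 11.7 ± 0.997 CPM, a log2 change of -2.13 ± 0.145 (edgeR adjusted p = 4.23e-15).

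DFR (AT5G42800), for a later step of the anthocyanin pathway, changed by 7.17 ± 0.635 with all libraries and by 8.23 without replicate 2 at 16 °C and light 10. The light-stress genes ELIP2 and LHCB4.3 (AT2G40100) rose by 3.79 ± 0.290 and 4.11 ± 0.246, MES18 by 6.64 ± 0.489 and CYP79F1 by 3.70 ± 0.490. ASN1 (AT3G47340), an asparagine synthetase gene, changed by -3.49 ± 0.289, and SLAH1 (AT1G62280) and TPX2 changed by -3.74 ± 0.251 and -3.91 ± 0.333. PAR1 (AT2G42870; -2.31 ± 0.260), HFR1 (-2.19 ± 0.269) and XTH15 (AT4G14130; -1.29 ± 0.187) were among the 11 of 19 growth genes that fell. CAB1 (AT1G29930; -2.07 ± 0.169) and LHCA4 (-1.63 ± 0.153) fell with LHB1B1, of which CAB1 and LHB1B1 have near-identical copies whose reads cannot be told apart here. Clock genes were lower in 14 of 22 cases, among them LCL1 (-1.88 ± 0.116) and PRR7 (AT5G02810; -1.19 ± 0.160), and the photoreceptor genes PHYA (AT1G09570) and CRY1 (AT4G08920) changed by -1.13 ± 0.121 and -0.73 ± 0.0771. With an estimated correlation the clock and light-signalling lists had an adjusted p = 0.0826 and 0.2. Higher were 13 of 14 Calvin cycle genes (SBPASE 0.68 ± 0.0917), 10 of 13 cell-cycle genes (CYCA1;1, AT1G44110, 1.23 ± 0.198) and 7 of 13 photoprotection genes, with an adjusted p = 0.2 for the Calvin cycle and 0.0826 for the cell-cycle list with an estimated correlation. Of 17 heat-shock genes 8 were higher (adjusted p = 0.55 with an estimated correlation), and the test of that list (median 1.02) lost its call with RLE scaling, without replicate 1 at 16 °C and light 100 (median 0.25) and without replicate 2 or 3 at 16 °C and light 10 (medians 1.07 and 0.79). Adjusted over the list alone, 16 flavonoid, 14 Calvin cycle and 11 cell-cycle genes were higher and 15 antenna, 15 clock and 11 growth genes were lower. The libraries at light 10 held the higher rRNA shares, and with that share as a covariate the change of PHYB (0.39 ± 0.0967) lost its call. With the covariate 5133 of the calls were kept, 3308 were lost and 1130 were gained. In all, 8441 genes were called, 3961 higher and 4480 lower at light 100.

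More light at 24 °C raised flavonoid, photoprotection and Calvin cycle genes and lowered growth genes in Col-0, and it raised aliphatic glucosinolate genes, a list drawn up after the data were seen. The Calvin cycle list was not past the threshold with an estimated correlation (adjusted p = 0.546). MAM1 (AT5G23010), a methylthioalkylmalate synthase gene of the glucosinolate pathway, rose from 1.83 ± 0.0759 to 148.5 ± 1.55 CPM (log2 change 6.34 ± 0.420, edgeR adjusted p = 2.11e-13). FMO GS-OX3 rose from 0.113 ± 0.0996 to 13.6 ± 0.628 CPM. The growth genes IAA29 (AT4G32280) and YUC8 (AT4G28720) changed by -2.44 ± 0.381 and -1.84 ± 0.302, and PIF4 by -0.23 ± 0.137 (edgeR adjusted p = 0.235).

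CYP79F1 changed by 10.31 with all libraries and was at least 2010-fold higher without replicate 3 at 24 °C and light 10, which left no counts at light 10, and BCAT4 (AT3G19710) changed by 8.93 with all and by 10.03 without replicate 1 of that group. MES18 was at least 125-fold higher at light 100 (2.92 ± 1.41 CPM, against no counts at light 10). The expansin gene EXPA16 (AT3G55500) fell from 22.2 ± 3.20 to 1.55 ± 0.227 CPM, and the cell-wall and transport genes ATPMEPCRD (AT2G43050), AGP7 (AT5G65390) and UMAMIT33 (AT4G28040) changed by -2.58 ± 0.166, -2.28 ± 0.363 and -2.27 ± 0.217. Of 16 flavonoid genes 15 were higher (median 2.73), among them FLS1 (AT5G08640; 2.76 ± 0.333) and TT4 (2.70 ± 0.304). LHCB4.3 (3.13 ± 0.240), ELIP2 (2.65 ± 0.300) and NPQ1 (AT1G08550; 1.05 ± 0.113) led 6 photoprotection genes, and CP12-2 (AT3G62410; 1.41 ± 0.143) led 8 of 14 Calvin cycle genes (adjusted p = 0.546 with an estimated correlation). Growth genes were lower in 10 of 19 cases and antenna genes in 9 of 17 (adjusted p = 0.546 with an estimated correlation), with LHB1B1 at -1.25 ± 0.186. Adjusted over the list alone, 15 flavonoid, 6 photoprotection and 8 Calvin cycle genes were higher and 12 growth and 10 antenna genes were lower. With the rRNA share as a covariate the antenna list lost its call and the called genes went from 6523 (3237 higher and 3286 lower at light 100) to 4320.

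The effect of warmth depended on light for cold-response, clock and flavonoid genes in Col-0. Positive values of this interaction mean a higher temperature effect at light 100 than at light 10. PIF4 had an interaction of 1.91 ± 0.197 (edgeR adjusted p = 4.22e-09), having risen by 0.74 at light 10 and by 2.65 at light 100. COR15B (2.88 ± 0.325) and LTI78 (1.92 ± 0.223) fell more at light 10, and the clock genes PRR7 (2.06 ± 0.225), FKF1 (1.79 ± 0.234), PRR5 (1.55 ± 0.182) and GI (AT1G22770; 1.03 ± 0.142) were all positive.

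TGG2 (AT5G25980), a myrosinase gene, had an interaction of 3.96 ± 0.243, while that of CYP79F1 was 6.61 with all libraries and at least 7.27 without replicate 3 at 24 °C and light 10, which left no counts in that group. Of 17 antenna genes 10 were positive and past the threshold (LHB1B1 2.12 ± 0.261, LHCA4 1.27 ± 0.212), as were the light-signalling genes LZF1 (AT1G78600; 1.13 ± 0.153) and CRY2 (AT1G04400; 0.74 ± 0.125). Both lists had an adjusted p = 0.128 with an estimated correlation. Negative values were seen for SP1L2 (AT1G69230; -2.48 ± 0.343), TBL26 (AT4G01080; -1.90 ± 0.254), BEE1 (AT1G18400; -1.74 ± 0.401), AUR2 (AT2G25880; -1.70 ± 0.306) and TT7 (AT5G07990; -1.24 ± 0.302). The Calvin cycle genes FBA1 (AT2G21330; -0.86 ± 0.216) and SBPASE (-0.53 ± 0.129) were also negative, in a list with an adjusted p = 0.59 with an estimated correlation. Adjusted over the list alone, 14 antenna, 11 clock, 10 light-signalling and 7 cold-response genes were positive and 3 flavonoid and 5 heat-shock genes were negative. The cell-cycle list had a median of -0.47 and was called with no single gene past the threshold, and with an estimated correlation it and the heat-shock list had an adjusted p = 0.128. In all, 1636 genes were called, 1039 positive and 597 negative, and 1029 were called without replicate 1 at 24 °C and light 100 and 2816 in a fit on Col-0 libraries alone.

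**Figure D4:**
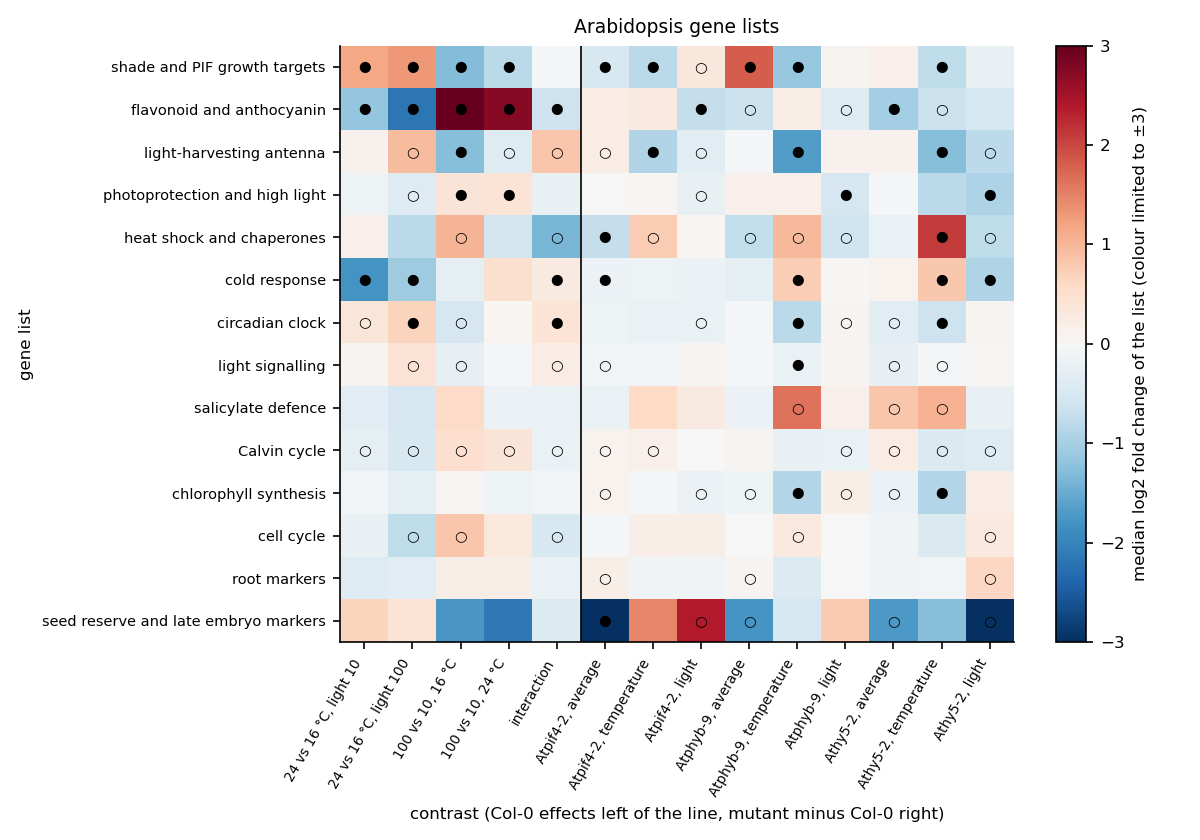
Each square is coloured by the median log2 change of 1 gene list (vertical axis) in 1 Arabidopsis comparison (horizontal axis), with a filled dot where the list test was past its threshold with both the preset and the estimated correlation between genes and an open dot where it was so with the preset only. The flavonoid list has medians of 3.60 and 2.73 for light and -1.15 and -2.16 for warmth in Col-0.

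Of the 70 tests of 14 gene lists over these 5 Col-0 comparisons, 36 passed the threshold with the preset correlation between genes. With an estimated correlation 17 of them held, namely growth, flavonoid and cold-response genes for both temperature effects, clock genes for warmth at light 100, growth, flavonoid and photoprotection genes for both light effects, antenna genes for light at 16 °C, and flavonoid, cold-response and clock genes for the interaction. The salicylate defence, root marker, seed reserve and chlorophyll synthesis lists were not called in Col-0.

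Light and temperature moved the same Arabidopsis genes in opposite directions more often than in the same direction. Of 5795 genes called for both average effects in Col-0, 2741 were higher with warmth and lower with more light, 2275 were lower with warmth and higher with more light, 421 were higher with both and 358 lower with both. HFR1 (2.52 ± 0.178 with warmth and -1.67 ± 0.176 with light) and PRE1 (3.15 ± 0.241 and -1.01 ± 0.235) were of the first kind, and the flavonoid gene TT5 (-1.13 ± 0.0975 and 1.61 ± 0.0984) of the second. Across all 22828 genes, which are not independent replicates, the average effects correlated at -0.272 ± 0.0411 (Pearson, jackknife SE over libraries; Spearman -0.399), at -0.164 without Col-0 replicate 3 at 16 °C and light 10 and at -0.179 with the rRNA share as a covariate. Temperature effects at light 10 and light 100 correlated at 0.391 ± 0.0275 (Spearman 0.552).

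**Figure D5:**
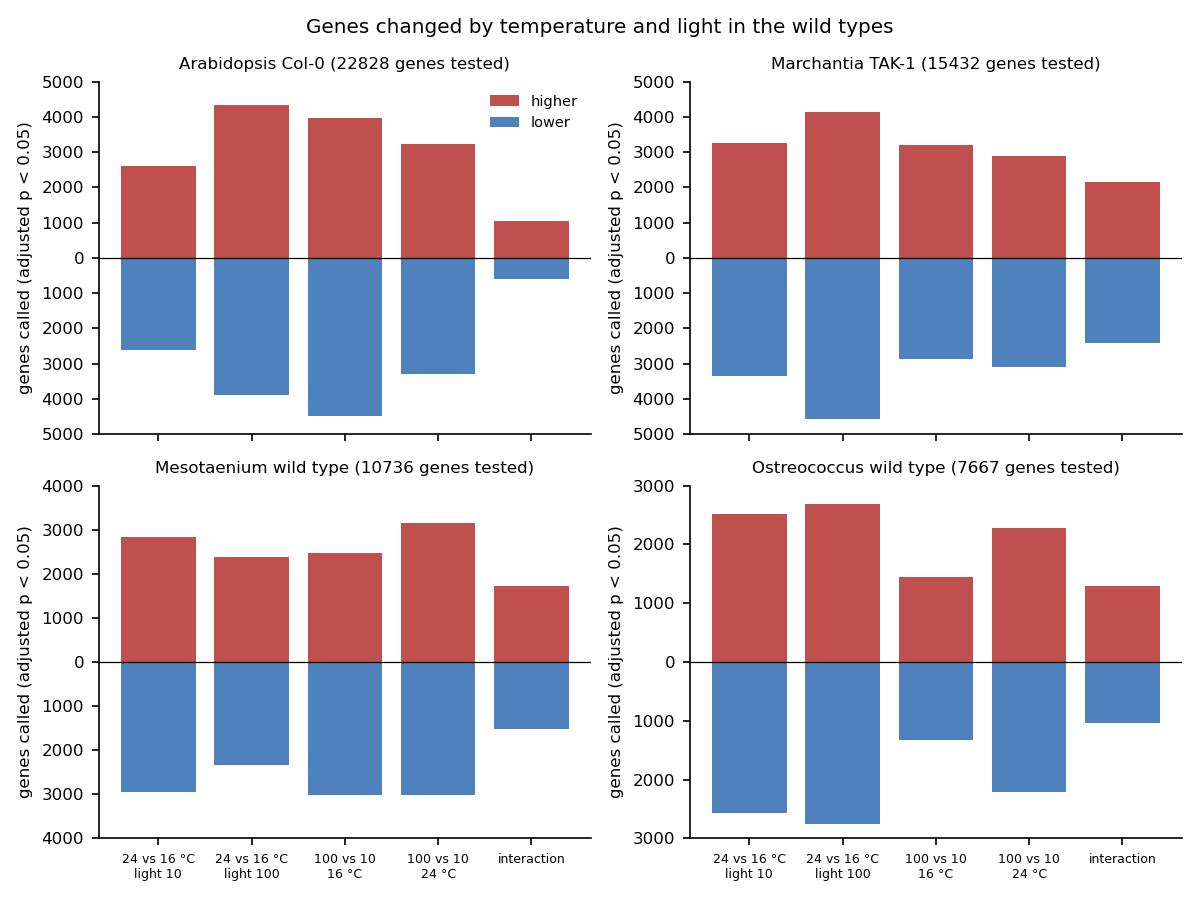
Bars give the numbers of genes called higher (above 0) and lower (below 0) in the wild type of each species for each temperature effect, light effect and interaction. In Arabidopsis 8441 genes are called for light at 16 °C and 1636 for the interaction.

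The Atpif4-2 line tested what the transcription factor PIF4 contributes. Growth genes were lower in Atpif4-2 on average over the conditions, as were heat-shock, cold-response and seed reserve genes and, in a list drawn up after the data were seen, jasmonate and touch genes. IAA29 was lower by a log2 difference of -1.51 ± 0.226, HB-2 (AT4G16780) by -0.74 ± 0.0998 and HFR1 by -0.75 ± 0.126. The temperature effect was lower in Atpif4-2 for 16 of 17 antenna genes, and for growth genes such as HFR1 (-1.53 ± 0.253). That of LHCA1 went from 0.751 ± 0.0856 in Col-0 to -0.376 ± 0.0852 in Atpif4-2 (difference -1.13 ± 0.121, edgeR adjusted p = 1.44e-08).

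Averaged over conditions, 10 of 19 growth genes were lower in Atpif4-2 (median -0.47; 12 adjusted over the list alone), 8 of 17 heat-shock genes, led by DREB2A (AT5G05410; -1.96 ± 0.266) and HSFA7A (AT3G51910; -1.20 ± 0.151), and 7 of 18 cold-response genes, led by CBF2 (AT4G25470; -2.99 ± 0.380) and CBF1 (AT4G25490; -2.86 ± 0.540). Of 11 jasmonate and touch genes 6 were lower (median -0.937, adjusted p = 1.05e-07 with the preset and 0.04 with an estimated correlation). The list was chosen from these data, so these p-values only describe these libraries. Its median level at 16 °C was 1.95 and 5.92 CPM in Atpif4-2 at light 10 and light 100 against 7.51 and 17.5 CPM in Col-0. That level was also below Col-0 in Atphyb-9 (1.57 and 3.38 CPM) and in Athy5-2 (2.2 and 4.7 CPM). The median average difference of the list was -0.923 in Atphyb-9, with 6 genes lower, and -0.00955 in Athy5-2, with 2 higher and 2 lower. DREB2A, CBF1, CBF2 and STZ (AT1G27730) were called lower in Atpif4-2 at both light levels at 16 °C and at neither at 24 °C. Seed reserve genes were lower in 9 of 10 cases (SESA1, AT4G27140, at least 183-fold on average, with no counts in Atpif4-2 at 24 °C and light 10), with the SESA genes being near-identical copies. STZ and EPR1 (AT2G27380) were lower by -2.80 ± 0.424 and -2.92 ± 0.511, and PCC1 (AT3G22231; 2.04 ± 0.334), PAO2 (AT2G43020; 1.89 ± 0.0576), ACD6 (AT4G14400; 1.09 ± 0.169) and TGG2 (0.98 ± 0.0835) were higher. PAO2 is the neighbour of PIF4 in the TAIR10.1 gene table. For the temperature effect, ADS1 (-1.92 ± 0.254), OFP16 (AT2G32100; -1.72 ± 0.288), CCL (AT3G26740; -1.57 ± 0.213) and PRE1 (-1.53 ± 0.331) were lower in Atpif4-2, and ORA47 (AT1G74930; 3.85 ± 0.786), WRKY40 (AT1G80840; 3.61 ± 0.824) and HSP70 (AT3G12580; 2.76 ± 0.366) higher. All of these are set against the Col-0 libraries at 16 °C, where touch and jasmonate genes were high and handling at harvest stays open. Among the genes that differed in the light effect were XPL1 (AT3G18000; 1.19 ± 0.152) and LHCB2.3 (AT3G27690; -1.01 ± 0.150). In the interaction, BBX16 (AT1G73870; 2.63 ± 0.365), LHCB2.1 (AT2G05100; 2.03 ± 0.331) and ABA1 (AT5G67030; 1.13 ± 0.209) were higher. Called were 3099 genes for the average difference (1582 higher), 2741 for temperature (1310 higher), 181 for light (131 higher) and 241 for the interaction (111 higher, 46.1%). The light number was 428 with DESeq2, 412 in a fit on Atpif4-2 and Col-0 libraries alone and 583 with the rRNA share as a covariate. The interaction number was 521 with DESeq2 and 648 in the fit on these libraries alone, 35.8% of them higher. With single libraries left out, the light number fell to 104 without Atpif4-2 replicate 2 at 24 °C and light 100, and the interaction number ran from 144 without Atpif4-2 replicate 1 of that group to 467 without Col-0 replicate 1 at 16 °C and light 10.

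The Atphyb-9 line tested the photoreceptor gene PHYB. All 19 growth genes were higher in Atphyb-9 on average (median 1.82), and antenna, clock and chlorophyll synthesis genes had a lower temperature effect than in Col-0. HFR1 was higher by 2.67 ± 0.122 (edgeR adjusted p = 1.13e-19) and IAA29 by 2.87 ± 0.196. The temperature effect of LHCB2.2 (AT2G05070) was 1.12 ± 0.118 in Col-0 and -1.27 ± 0.118 in Atphyb-9 (difference -2.38 ± 0.167, edgeR adjusted p = 3.61e-14), and that of PIF4 differed by -1.92 ± 0.139.

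ST2A (AT5G07010), a sulfotransferase gene, was among the genes with the largest average increases in Atphyb-9 (2.86 ± 0.129), with ADS1 (2.61 ± 0.121), ATPMEPCRD (2.40 ± 0.0816), FAR1 (AT5G22500; 1.91 ± 0.105) and XTH15 (1.62 ± 0.0925). DREB2A (-2.14 ± 0.269) and SESA2 (AT4G27150; -3.68 ± 0.844) were lower, as were DFR and CYP91A2 (AT4G37430), by at least 3.33-fold and 3.24-fold on average, with no counts in Atphyb-9 at light 10 and 24 °C or 16 °C. For the temperature effect, 16 of 17 antenna genes (median -1.68), 13 of 22 clock genes, 12 of 19 growth genes, 11 of 26 light-signalling genes and 10 of 13 chlorophyll synthesis genes were lower in Atphyb-9, the same numbers adjusted over the list alone except 12 light-signalling genes. PRE1 (-3.18 ± 0.319), OFP16 (-2.85 ± 0.291), GUN4 (AT3G59400; -2.40 ± 0.425), LHCB3 (-2.15 ± 0.130), CH1 (AT1G44446; -1.61 ± 0.120) and STO (-1.54 ± 0.103) were among them. Cold-response genes went the other way in 11 of 18 cases, among them COR15B (1.92 ± 0.222) and GRP7 (AT2G21660; 1.32 ± 0.165), as did the salicylate gene WRKY70 (AT3G56400; 3.03 ± 0.519), in a list with an adjusted p = 0.0954 with an estimated correlation. For the light effect, ELIP2 (-1.93 ± 0.274), XTH15 (-1.77 ± 0.182) and LHCB4.3 (-1.32 ± 0.225) were lower and PIF4 (0.90 ± 0.138) and PRR5 (0.79 ± 0.128) higher. In the interaction, ADS1 (4.03 ± 0.472), BBX16 (3.05 ± 0.364) and GBSS1 (AT1G32900; 2.71 ± 0.337) were higher and COR15B (-3.94 ± 0.445), FKF1 (-2.89 ± 0.333), PRR7 (-2.48 ± 0.316) and PRR5 (-2.37 ± 0.257) lower. Called were 7683 genes for the average difference (3907 higher), 5141 for temperature (2317 higher), 1808 for light (1033 higher) and 644 for the interaction (275 higher). The Atphyb-9 libraries at 24 °C and light 10 held 13% rRNA counts on average, and replicate 1 at 24 °C and light 100 held 9.37%. With the rRNA share as a covariate 5380 genes were called for the average difference, 5056 of them among the 7683, and 5277 for temperature, 4105 of them among the 5141.

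The Athy5-2 line tested the transcription factor HY5. Flavonoid genes were lower in the libraries labelled Athy5-2 on average, and the temperature effect was lower for antenna, chlorophyll synthesis, clock and growth genes and higher for heat-shock and cold-response genes. F3H was lower by -2.17 ± 0.131 (edgeR adjusted p = 2.4e-15) and TT4 by -1.86 ± 0.150. The temperature effect of LHCB2.3 was 0.368 ± 0.106 in Col-0 and -2.07 ± 0.11 in Athy5-2 (difference -2.44 ± 0.152, edgeR adjusted p = 5.29e-15), and that of CH1 was 0.412 ± 0.0847 and -1.30 ± 0.0863 (difference -1.72 ± 0.121).

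PRR1 (AT1G32100), a pinoresinol reductase gene, had an average decrease of -3.37 ± 0.0985 in the libraries labelled Athy5-2, and 9 of 16 flavonoid genes were lower (median -1.02; 9 adjusted over the list alone). The clock genes LHY (AT1G01060) and CCA1 (AT2G46830) were lower by -1.21 ± 0.0816 and -0.94 ± 0.0924 (adjusted p of the clock list 0.284 with an estimated correlation), and PXMT1 (AT1G66700; 3.32 ± 0.298), PCC1 (2.97 ± 0.338), GSTU12 (AT1G69920; 2.48 ± 0.390) and GLP4 (AT1G18970; 2.31 ± 0.208) were higher. For the temperature effect, 16 of 17 antenna, 12 of 13 chlorophyll synthesis, 13 of 22 clock and 9 of 19 growth genes were lower, each number the same adjusted over the list alone. LEA18 (-2.69 ± 0.346), BGLU19 (AT3G21370; -2.81 ± 0.716), PRE1 (-2.97 ± 0.326) and PIF4 (-1.15 ± 0.139) were among the lower genes, and HSF4 (AT4G36990; 2.19 ± 0.272), COR15A (1.98 ± 0.332) and LTI78 (1.14 ± 0.157) among the higher ones. For the light effect, 7 of 13 photoprotection genes (APX1, AT1G07890, -1.26 ± 0.151) and 10 of 18 cold-response genes (COR15B -2.14 ± 0.223, KIN2 -1.74 ± 0.211) were lower, while MSL9 (AT5G19520; 1.79 ± 0.304), EXT13 (AT5G35190; 1.71 ± 0.426) and HRGP1 (AT3G54590; 1.70 ± 0.418) were higher. Called were 10441 genes for the average difference (5196 higher), 6578 for temperature (2894 higher), 5961 for light (3057 higher) and 2474 for the interaction (734 higher). The libraries at light 10 and 24 °C held 19.2% rRNA counts on average, and with the rRNA share as a covariate the interaction count was 415, and 8757 genes were called for the average difference, 8505 of them among the 10441. The temperature and light effects set that group against groups with means of 5.26% (16 °C, light 10) and 0.344% (24 °C, light 100). With the covariate their numbers stayed within 1.5 times, which does not say which genes kept their call.

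Over the 3 lines, 83 of 168 list tests passed the threshold, and 26 of them held with an estimated correlation. Those 26 were, for Atpif4-2, growth, heat-shock, cold-response and seed reserve genes on average, growth and antenna genes for temperature, flavonoid genes for light and photoprotection genes for the interaction. For Atphyb-9 they were growth genes on average, growth, antenna, cold-response, clock, light-signalling and chlorophyll genes for temperature, photoprotection genes for light and cold-response genes for the interaction. For Athy5-2 they were flavonoid genes on average, growth, antenna, heat-shock, cold-response, clock and chlorophyll genes for temperature, and photoprotection and cold-response genes for light.

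The 3 mutant lines were compared with each other gene by gene. All of them share the Col-0 libraries, so unchanged lines would also correlate. Average differences of Atphyb-9 and Athy5-2 correlated at 0.466 ± 0.0419, against 0.493 in simulations of unchanged lines, with a covariance of 0.178 against 0.0433, and at 0.343 with the Col-0 libraries split between the lines. Those of Atpif4-2 and Atphyb-9 correlated at 0.346 ± 0.0285 (simulated 0.513; covariance 0.108 against 0.0443; split controls 0.202), and those of Atpif4-2 and Athy5-2 at 0.306 ± 0.0354 (simulated 0.493; covariance 0.104 against 0.0433; split controls 0.204). Genes higher in both Atphyb-9 and Athy5-2 numbered 2448 (889 for independent lists), genes lower in both 2416 (868) and genes called in opposite directions 339. For Atpif4-2 with Atphyb-9 these were 704 (271), 679 (251) and 387, and for Atpif4-2 with Athy5-2 1016 (360), 757 (349) and 239. With the Col-0 libraries split between the lines, genes higher in both and lower in both numbered 1402 and 1233 for Atphyb-9 and Athy5-2 (442 and 362 for independent lists), with 160 in opposite directions. These were 168 and 178 (61 and 50) with 147 opposite for Atpif4-2 and Atphyb-9, and 331 and 224 (94 and 84) with 51 opposite for Atpif4-2 and Athy5-2. Over the 9690 genes called for temperature in Col-0, the mutants kept shares of the Col-0 response of 0.586 ± 0.0693 (Atpif4-2), 0.395 ± 0.0427 (Atphyb-9) and 0.629 ± 0.0601 (Athy5-2). Over the 10404 genes called for light the shares were 0.938 ± 0.0533, 1.00 ± 0.0577 and 1.12 ± 0.0743.

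In wild-type Marchantia (TAK-1) warmth changed more genes at light 100 than at light 10, and named genes cannot be given because the files do not pair identifiers with names. Mp2g18790 rose with warmth at light 100 from 0.825 ± 0.314 to 87.2 ± 3.55 CPM, and with light at 24 °C from 0.0621 ± 0.0538 to 87.2 ± 3.55 CPM. Mp6g13520 fell with warmth at light 10 from 18.9 ± 2.16 to 0.512 ± 0.127 CPM (log2 change -5.20 ± 0.299, edgeR adjusted p = 6.39e-16), and Mp7g08130 was at least 14.8-fold lower. At light 100, Mp2g26440 and Mp2g26460 had no counts at 24 °C and were at least 1960-fold and 1640-fold lower than at 16 °C, where their levels differed between libraries (42.3 ± 39.0 and 35.3 ± 29.8 CPM). Without replicate 1 at 16 °C and light 100 they were at least 928-fold and 854-fold lower. Light at 16 °C lowered Mp2g16000 from 48.2 ± 3.88 to 1.90 ± 0.231 CPM, light at 24 °C raised Mp6g12780 from 0.373 ± 0.122 to 63.3 ± 11.5 CPM, and Mp5g21410 had an interaction of 5.51 ± 0.419. Called were 6599 of 15432 genes for warmth at light 10 (3259 higher), 8705 at light 100 (4142 higher), 6075 for light at 16 °C (3213 higher), 5969 at 24 °C (2877 higher) and 4561 for the interaction (2139 positive).

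The Marchantia lines Mppif-1, Mpphy-1 and Mphy5-1 carry mutations in the Marchantia counterparts of these regulators, by their labels. On average, Mp5g07320 was at least 18.3-fold lower in Mppif-1, where it had no counts at 16 °C and light 10, Mp1g10370 was lower in Mpphy-1 (-6.73 ± 0.237), and Mp2g18620 was lower (-3.22 ± 0.133) and Mp7g02340 higher (1.86 ± 0.316) in Mphy5-1. The temperature effect of Mp5g04550 was lower in Mppif-1 (-3.35 ± 0.418) and in Mpphy-1 (-7.80 ± 0.567), as was that of Mp5g04630 (-3.60 ± 0.627 and, with no counts in Mpphy-1 at 24 °C and light 10, at least 162-fold). Mp2g13460 (5.85 ± 0.428) had a higher temperature effect in Mppif-1 and Mp5g04650 (-5.16 ± 0.453) a lower one in Mphy5-1. For the light effect, Mp5g10170, with no counts in Mppif-1 at 16 °C and light 10, was at least 13-fold higher in Mppif-1, and in Mpphy-1 Mp7g09340, with no counts at light 10, was at least 17.2-fold higher and Mp8g16290 lower (-3.94 ± 0.549). In the interaction, Mp5g07800, with no counts in Mpphy-1 at 16 °C and light 10, was at least 29.5-fold lower in Mpphy-1, and Mp8g04310 (-3.91 ± 0.698) and Mp1g10370 (-3.77 ± 0.612) in Mphy5-1.

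Called for the average difference, temperature, light and interaction were 8162, 3698, 2405 and 2594 genes in Mppif-1, 10449, 7266, 4897 and 2328 in Mpphy-1, and 5801, 3400, 2493 and 407 in Mphy5-1, the last being 236 without TAK-1 replicate 3 at 24 °C and light 10 and 725 with DESeq2. Over genes called in TAK-1, Mpphy-1 kept 0.372 ± 0.0433 of the light response and 0.769 ± 0.0442 of the temperature response, Mppif-1 0.727 ± 0.0237 and 0.811 ± 0.0244, and Mphy5-1 0.912 ± 0.0283 and 1.15 ± 0.0299. Average differences correlated at 0.563 ± 0.0399 for Mppif-1 and Mpphy-1 (0.509 in simulations; covariance 0.403 against 0.0294; 0.497 with split controls). For Mppif-1 and Mphy5-1 the correlation was 0.526 ± 0.0428 (simulated 0.496; covariance 0.164 against 0.0287; split 0.375), and for Mpphy-1 and Mphy5-1 it was 0.325 ± 0.0576 (simulated 0.507; covariance 0.181 against 0.0286; split 0.257). Genes higher in both Mppif-1 and Mpphy-1 numbered 2059 (1340 for independent lists), genes lower in both 2487 (1420) and genes called in opposite directions 1832. For Mppif-1 with Mphy5-1 the numbers were 1831 (784), 1962 (750) and 448, and for Mpphy-1 with Mphy5-1 1534 (973), 1708 (989) and 1299. With the TAK-1 libraries split between the lines, genes higher in both and lower in both numbered 1554 and 1940 for Mppif-1 and Mpphy-1 (983 and 1025 for independent lists), with 1432 in opposite directions. These were 1113 and 1358 (444 and 454) with 282 opposite for Mppif-1 and Mphy5-1, and 922 and 1196 (585 and 641) with 874 opposite for Mpphy-1 and Mphy5-1.

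In the alga Mesotaenium the gene that the files name MEPIF responded to light and not detectably to temperature. It fell with more light from 348.2 ± 10.6 to 188.9 ± 7.76 CPM at 16 °C (log2 change -0.88 ± 0.0811, edgeR adjusted p = 8.19e-07) and from 336.5 ± 24.5 to 183.4 ± 9.99 CPM at 24 °C. Its temperature effects were -0.05 ± 0.0804 at light 10 (edgeR adjusted p = 0.627) and -0.04 ± 0.0805 at light 100 (edgeR adjusted p = 0.695), and its interaction was 0.01 ± 0.114.

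ME000401S07011 rose with warmth by 5.21 ± 0.499 at light 10 and 5.53 ± 0.515 at light 100, and ME000364S06164 fell by at least 26.5-fold at light 10 and by a log2 change of -8.05 ± 0.153 at light 100. Light raised ME000364S06164 from 0.784 ± 0.137 to 291.1 ± 17.8 CPM at 16 °C and at least 37.1-fold at 24 °C. ME000698S09225 fell with light at 16 °C (-6.29 ± 0.215) and ME000099S10520 at 24 °C (-6.55 ± 0.198), and ME000240S03785 had an interaction of 5.86 ± 0.381. Called were 5787 of 10736 genes for warmth at light 10, 4725 at light 100, 5488 for light at 16 °C, 6170 at 24 °C and 3237 for the interaction.

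In the alga Ostreococcus the mitochondrial gene entries Cox1_1 and Cox1_2, which had nearly the same counts, rose with warmth and with light at 16 °C. Cox1_2 rose with warmth from 2.06 ± 0.237 to 16.7 ± 5.80 CPM at light 10 (log2 change 3.02 ± 0.276, edgeR adjusted p = 6.61e-07) and from 4.97 ± 1.64 to 16.0 ± 1.67 CPM at light 100. Its light effect at 16 °C was 1.27 ± 0.277 and its interaction -1.34 ± 0.369. The share of all mitochondrial entries in the counts did not rise with warmth at light 10. There it ran from 0.0763% to 0.101% at 16 °C and from 0.0348% to 0.0485% at 24 °C. At light 100 it ran from 0.0520% to 0.135% at 16 °C and from 0.0481% to 0.163% at 24 °C.

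OT_ostta13g01100 rose with warmth at light 10 (4.37 ± 0.226) and with light at 16 °C (3.15 ± 0.216), as did OT_ostta05g02880 (4.34 ± 0.345 and 3.14 ± 0.341). OT_ostta04g03630 changed with warmth by -4.90 ± 0.148 at light 10 and by -5.26 ± 0.159 at light 100, and OT_ostta16g01140 was at least 597-fold lower with warmth at light 10, having no counts at 24 °C and light 10, and at least 376-fold higher with light at 24 °C. OT_ostta19g00075 rose with warmth at light 100 (5.41 ± 0.164), and OT_ostta10g00930 (-8.81 ± 0.482) and OT_ostta10g00920 (-8.19 ± 0.389) fell with light at 24 °C. Called were 5084 of 7667 genes for warmth at light 10, 5455 at light 100, 2786 for light at 16 °C, 4482 at 24 °C and 2337 for the interaction.

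Set side by side, the average temperature and light effects opposed each other in Arabidopsis and went the same way in Ostreococcus. Of the genes called for both, opposite signs were seen in 86.6% of 5795 genes in Arabidopsis, 57.6% of 4509 in Marchantia, 42.5% of 4354 in Mesotaenium and 23.1% of 3585 in Ostreococcus. The Pearson correlations across genes were -0.272 ± 0.0411, -0.106 ± 0.0566, -0.0861 ± 0.0781 and 0.541 ± 0.0377 in that order, with Spearman values of -0.399, -0.115, 0.0905 and 0.451. For Arabidopsis the Pearson value was -0.164 without Col-0 replicate 3 at 16 °C and light 10 and -0.179 with the rRNA share as a covariate. For Marchantia it was -0.0136 without replicate 1 at 16 °C and light 10. For Mesotaenium it lay between -0.17 and 0.0092 when single libraries were left out, turning positive without replicate 1 at 16 °C and light 10. Temperature effects at light 10 and light 100 correlated at 0.0453 ± 0.123 in Marchantia (Spearman 0.470; 0.196 without TAK-1 replicate 3 at 24 °C and light 10), 0.495 ± 0.0260 in Mesotaenium and 0.801 ± 0.0378 in Ostreococcus. The species differed in age, tissue and number of genes, and differences between species were not tested.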

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

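The interactions and the differences between lines in this part were found by testing the difference itself with edgeR. The touch and jasmonate genes, the rRNA share and LHB1B2 were taken up from group medians or the scatter between replicates, with no such test. The tests of scatter between replicates for the touch and jasmonate list, of the calls lost with the rRNA share, of the common shift from rRNA, and both tests for LHB1B2 were chosen only after the result was seen, and that list was itself drawn up after the data were seen.

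The effect of warmth differed between the light levels in each wild type. In Arabidopsis 1636 genes were called, while random splits of the 12 Col-0 libraries called up to 8000, and 5 of the 25 splits reached the real number or more, the real one included. In Marchantia 4561 genes were called against at most 8296 in other splits, and in Ostreococcus 2337 against at most 4512, with 2 of 31 splits reaching the real number in each. In Mesotaenium 3237 genes were called and at most 2280 in other splits. The splits that called more genes than the real one point to the large light and temperature differences among these libraries, which a random regrouping moves into the interaction. Such splits are no measure of chance alone, so in none of the 4 species do they decide whether chance can be excluded.

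The temperature effect differed from Col-0 for 2741 genes in Atpif4-2 (other splits at most 2583), 5141 in Atphyb-9 (at most 6680) and 6578 in Athy5-2 (at most 10036), with 2 of 25 splits reaching the real number in each of the last 2, the real one included. The light effect differed for 181 genes in Atpif4-2 (at most 896), 1808 in Atphyb-9 (at most 756) and 5961 in Athy5-2 (at most 3245), and the interaction for 241 (at most 123), 644 (at most 2329) and 2474 (at most 5203). Line labels were exchanged within each condition, so a split that mixes the labels in some conditions more than in others moves the average difference of a line into its other differences, and here and in Marchantia the splits do not decide whether chance can be excluded, whether or not they reach the real number.

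In Marchantia the temperature effect differed from TAK-1 for 3698 genes in Mppif-1 (other splits at most 6392, with 3 of 31 splits reaching the real number), 7266 in Mpphy-1 (at most 8290) and 3400 in Mphy5-1 (at most 3600). The light effect differed for 2405 genes in Mppif-1 (at most 3467), 4897 in Mpphy-1 (at most 2612) and 2493 in Mphy5-1 (at most 666), and the interaction for 2594 (at most 2270), 2328 (at most 5738) and 407 (at most 856).

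Touch and jasmonate genes (TCH2, TCH3, TCH4, JAZ1, JAZ5, JAZ7, JAZ8, JAZ10, LOX3, LOX4 and MYC2) were high in Col-0 at 16 °C, with medians of 7.51 CPM at light 10 and 17.5 CPM at light 100, against 1.81 and 3.29 CPM at 24 °C, and Athy5-2 at 24 °C held 14.1 and 7.58 CPM. The median log2 change of the list with warmth at light 100 was -2.12 with a jackknife error of 1.03, and with the rRNA share as a covariate it was -2.39. At light 100 the Col-0 groups hardly differed in that share (means of 0.623% at 16 °C and 0.449% at 24 °C). The covariate could therefore move the median little and decides nothing about the share. At light 10, with means of 6.76% and 3.19%, the covariate was not tried on this list. Without replicate 1 at 16 °C and light 100 the median at light 100 was -1.09, about 1 error from the value with all libraries. At light 10 the median went from -1.41 to -0.269 without replicate 1 at 16 °C and light 10, so a part played by these libraries stays open. The scatter of these genes between the replicates of Col-0 at 16 °C lay at percentile 100 of 10000 random lists matched on expression. Since the list was chosen from these data, that test decides nothing about handling at harvest, which stays open beside temperature and genotype, which the design varies. The same holds for the lower levels of this list, DREB2A, CBF1, CBF2 and STZ in Atpif4-2 at 16 °C, which are set against these Col-0 libraries. Differences in temperature effect are set against them too, with list medians of 2.06 in Atpif4-2, 2.22 in Atphyb-9 and 3.53 in Athy5-2. So are those of ORA47 and WRKY40 in Atpif4-2 and the average difference of DREB2A in Atphyb-9. A part played by handling in them was not tested. At 16 °C the list was at 1.95 and 5.92 CPM in Atpif4-2 at light 10 and light 100. It was at 1.57 and 3.38 CPM in Atphyb-9 and at 2.2 and 4.7 CPM in Athy5-2, so Col-0 stood above each mutant line.

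The share of counts on rRNA genes was higher at light 10 than at light 100 in Arabidopsis, with medians of 5.71% and 0.547%. Without the rRNA genes 8437 genes were called for light at 16 °C in Col-0, against 8441 with them, but none of 17 numbers of called genes moved by more than 2.22% in that setting, so it decides nothing. Counts taken up by rRNA lower the others by 1 factor, at most 0.129 on the log2 scale for these libraries. Of the 8441 genes 7458 lay more than 2 SE beyond it, 3497 higher and 3961 lower at light 100. TMM scaling had already taken out a factor common to the other genes, so this outcome was set beforehand. It decides nothing about other ways in which the share could matter. In the Col-0 libraries at 16 °C the share ran from 4.90% to 9% at light 10 and from 0.480% to 0.799% at light 100. A covariate carries the trend found within groups across that gap, so it cannot tell the share from light. With the share as a covariate 6263 genes were called for this effect, 5133 of them among the 8441. That argues only against a trend of the size seen within groups as the cause of these 5133. The other 3308 lost their call, with a median log2 change of 0.603 before (median SE 0.173) and 0.356 after (median SE 0.212), so both a smaller change and a larger error ended their calls and the trend stays open for them, as it does for the calls lost for light at 24 °C (3651 of 6523 kept), for the interaction difference of Athy5-2 (357 of 2474 kept) and for the average difference of Atphyb-9 (5056 of 7683 kept). Light itself, which the design varies together with the share, was not tested as a source of the share.

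LHB1B2 (AT2G34420), an antenna gene that the noncoding gene AT2G08665 overlaps in the TAIR10.1 gene table, had counts in some replicates and none in others in 12 of 16 groups, with 0 to 15520 CPM in Col-0 at 16 °C and light 10. The summed CPM of both scattered less than LHB1B2 alone in 2 of 14 groups, but the overlapping gene itself scattered more than LHB1B2 in 12 of them and the sum scattered less than the overlapping gene in 11 of them, so that comparison could not decide. Within groups the slope of the overlapping gene on LHB1B2 was -1.38 ± 0.20 (SE, 42 libraries), and a passing of counts from 1 gene to the other, for which -1 is predicted, is a candidate explanation. Without the group of Col-0 at 16 °C and light 10 the slope was -1.89 ± 0.274, farther from -1. No biological explanation was tested, and LHB1B2 stays in the antenna list, whose 17 tests with the preset correlation kept their side of the threshold and direction without it.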

How the results depend on the processing

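Leaving out the rRNA genes, the rRNA share as a covariate, leaving out the 2 shallow Ostreococcus libraries and the antenna list without LHB1B2 were chosen after the data were seen. Most numbers of called genes stayed within 1.5 times: all 44 with RLE scaling and with no low-count filter, 41 of 44 with DESeq2 and 31 of 34 with fits on the compared lines alone. Of named genes, 744 of 772 kept their side of the threshold and direction with DESeq2 (6 lost and 22 gained a call), 775 of 778 with RLE scaling, 768 of 778 with no filter, 665 of 712 with the compared lines alone (29 lost and 18 gained), and 613 of 644 with the rRNA covariate. Most named genes were picked as called genes with the largest changes or the smallest adjusted p. That most kept their call, here and with single libraries left out, was therefore likely beforehand and says little about other calls. Leaving out the rRNA genes moved none of 17 numbers of called genes by more than 2.22%, which is no test of stability.

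DESeq2 called 428 genes for the light difference of Atpif4-2 in place of 181, 521 for its interaction difference in place of 241, and 725 for the interaction difference of Mphy5-1 in place of 407. With Atpif4-2 and Col-0 libraries alone these Atpif4-2 numbers were 412 and 648, and with Col-0 libraries alone 2816 genes were called for the Col-0 interaction in place of 1636. The rRNA covariate gave 4320 genes for light at 24 °C in Col-0 in place of 6523, 583 for the light difference of Atpif4-2 and 415 for the interaction difference of Athy5-2 in place of 2474. With it the correlation of temperature and light effects in Col-0 was -0.179, that of Atpif4-2 and Atphyb-9 was 0.307, and the shares of the light response kept were 0.866, 0.889 and 0.944 for Atpif4-2, Atphyb-9 and Athy5-2. With an estimated correlation 17 of 36 list calls in Col-0 and 26 of 83 in the mutants were left. Without LHB1B2 the antenna list kept its side of the threshold in 17 of 17 tests with the preset correlation, and 16 of 16 antenna genes were lower for the temperature effect in Atpif4-2, Atphyb-9 and Athy5-2 (medians -0.923, -1.69 and -1.3). With the estimated correlation its adjusted p for light at 16 °C in Col-0 went from 0.0496 to 0.0566. With no low-count filter the correlation of temperature and light effects in Col-0 was -0.196 and that of its temperature effects 0.283, those of Atpif4-2 with Atphyb-9 and Athy5-2 were 0.401 and 0.399, and those of temperature effects in Mesotaenium and Ostreococcus were 0.468 and 0.760. The cause was not tested, except that no filter adds genes with few counts.

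With single libraries left out, 709 of 720 numbers of called genes stayed within 1.5 times and 13203 of 13734 values of named genes kept their side of the threshold and direction. The Col-0 interaction ran from 1029 (without replicate 1 at 24 °C and light 100) to 1540 genes. The light difference of Atpif4-2 ran from 104 (without Atpif4-2 replicate 2 at 24 °C and light 100) to 238, with 113 without Col-0 replicate 2 at 24 °C and light 10. Its interaction difference ran from 144 (without Atpif4-2 replicate 1 at 24 °C and light 100) to 467 (without Col-0 replicate 1 at 16 °C and light 10), with 157, 158 and 159 without Col-0 replicate 2 at 16 °C and light 10, Atpif4-2 replicate 1 at 24 °C and light 10 and Col-0 replicate 3 at 24 °C and light 100. The interaction difference of Mphy5-1 ran from 236 (without TAK-1 replicate 3 at 24 °C and light 10) to 507, with 259 and 266 without Mphy5-1 replicate 1 at light 10 and 24 °C or 16 °C.

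Correlations of temperature and light effects ran from -0.317 to -0.164 in Col-0, from -0.206 to -0.0136 in TAK-1 and from -0.17 to 0.0092 in Mesotaenium, where the sign turned without replicate 1 at 16 °C and light 10. Those of temperature effects at both light levels ran from 0.343 to 0.394 in Col-0, 0.0232 to 0.196 in TAK-1 (the latter without replicate 3 at 24 °C and light 10), 0.459 to 0.498 in Mesotaenium and 0.752 to 0.808 in Ostreococcus. Those of average differences ran from 0.328 to 0.381 for Atpif4-2 and Atphyb-9, 0.302 to 0.369 for Atpif4-2 and Athy5-2, 0.437 to 0.518 for Atphyb-9 and Athy5-2 and 0.308 to 0.391 for Mpphy-1 and Mphy5-1. The light difference of KIN1 in Athy5-2 was -3.04 with all libraries, and its fitted values ran from -3.56 to 0.46, the latter without Athy5-2 replicate 2 at 24 °C and light 10. That library held the 22 counts of its group, so the fitted 0.46 rests on a group with no counts and its reversed sign is no measurement. The cause was not tested.

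With the replicate number as a block, 5134 genes were called for warmth at light 10 in Col-0, 5062 of them among the 5213 called without it. The block moved 0 of 44 numbers by over 1.5 times, and of 778 values of named genes 8 lost and 2 gained a call. Deviations of libraries with the same number correlated at -0.00333 in Arabidopsis, 0.0113 in Marchantia, 0.00774 in Mesotaenium and 0.0326 in Ostreococcus on average. Over 0.1 were 8 of 360 pairs, 29 of 360, 1 of 18 and 9 of 18 (Ostreococcus from -0.271 to 0.385), so not each pair was over 0.1 in any species and the numbers were not taken to pair the libraries. Without the 2 shallow Ostreococcus libraries 8 of 41 values of named genes lost their call and 0 of 5 numbers of called genes moved by over 1.5 times. Depth limits genes with few counts, and a group with 0 counts gives only a lower bound on a fold change, as for MES18 in Col-0 at 24 °C and light 10.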

Other observations

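The 3 lists in this part were drawn up after the data were seen, so their tests are descriptions of these libraries. Of 18 aliphatic glucosinolate synthesis genes, 17 were lower with warmth at light 10 in Col-0 (median -2.74) and 10 at light 100 (median -0.59), 18 were higher with light at 16 °C (median 2.84) and 17 at 24 °C (median 4.82), and 11 had a positive interaction and 1 a negative one. In Atphyb-9 the temperature effect was higher for 16 of them (median 2.37), in Athy5-2 for 16 (median 1.55) and in Atpif4-2 for 10 (median 0.92). The interaction was lower for 10 of them in Atphyb-9 (median -2.62) and for 12 in Athy5-2 (median -2.24). The 3 lines are set against the same Col-0 libraries, so these differences are not independent of each other. Of 7 indole glucosinolate genes, 4 were lower with warmth at light 10 (median -0.65; 1 and -0.362 without Col-0 replicate 1 at 16 °C and light 10) and 5 higher with light at 24 °C (median 0.87). Of 11 jasmonate and touch genes, 4 were lower with warmth at light 10 (median -1.41) and 5 at light 100 (median -2.12). Without Col-0 replicate 1 at 16 °C and light 10 the median at light 10 was -0.269 with 1 gene lower, and without replicate 1 at 16 °C and light 100 the median at light 100 was -1.09 with 3 genes lower. The calls of this list for warmth were lost with an estimated correlation (adjusted p = 0.225 at light 10 and 0.282 at light 100), as were those of the indole list for warmth at light 10 (0.225) and of the aliphatic list for warmth at light 100 (0.282).

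The number of genes called as different between a line and its wild type varied with the condition. For Atpif4-2 it was 4723 at 16 °C and light 10, 1090 at 16 °C and light 100, 973 at 24 °C and light 10 and 102 at 24 °C and light 100. For Atphyb-9 these numbers were 6672, 2916, 4013 and 2484, and for Athy5-2 6449, 5073, 10609 and 2982. The highest number of Athy5-2 was in the group with the highest rRNA share. All libraries share 1 estimate of the spread per gene, but the groups did not scatter alike. At 24 °C and light 10, deviations of log2 CPM from the group mean had SDs of 0.584 to 0.684 across genes in Athy5-2. At 24 °C and light 100 they had SDs of 0.275 to 0.315. The numbers therefore do not compare the size of a line's difference between conditions.

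For the simple effects, the 10 splits of 6 libraries are too few for a share under 0.05. In Col-0 the real values were 5213 and 8201 genes for warmth at light 10 and light 100 and 8441 and 6523 for light at 16 and 24 °C, and the highest other splits called 0, 6, 230 and 0. In TAK-1 they were 6599, 8705, 6075 and 5969, with 1 gene in the highest other split of each. In Mesotaenium they were 5787, 4725, 5488 and 6170 and in Ostreococcus 5084, 5455, 2786 and 4482, with 0 genes in each other split. For the average differences no other split called as many genes as the real one, among 25 splits in Arabidopsis and 31 in Marchantia. That share of splits is under 0.05 in each line and argues against chance for each line taken alone. It was not adjusted over the lines. The numbers were 3099 genes in Atpif4-2 (other splits at most 1432), 7683 in Atphyb-9 (at most 2631) and 10441 in Athy5-2 (at most 3246). In Marchantia they were 8162 in Mppif-1 (at most 6242), 10449 in Mpphy-1 (at most 7287) and 5801 in Mphy5-1 (at most 2856).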
